A study of Mus musculus with 2 samples.

How the data were processed

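Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-Lef1 antibody (clone C18A7) on sorted mouse CD4+ T cells. Lef1 is a DNA-binding protein of the TCF/LEF family. The study holds 2 libraries, 1 from wild-type conventional CD4+ T cells and 1 from Lef1-deficient CD4+ T cells made by deleting a floxed Lef1 gene with CD4-Cre. The labels describe the wild-type cells as conventional and CD25-negative and the Lef1-deficient cells as all CD4 T cells. They also give naive CD4 T cells as the tissue of both, so whether naive cells were selected is uncertain, as is whether the gates of the 2 libraries differed. The Lef1-deficient library entered only as the background control of the peak calls, per the labels. No library was replicated, so no comparison between samples could be tested.

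The analysis started from the single deposited list of 2052 peaks. Each peak has a position and a deposited score, which is the −log10 of the peak caller's p-value per the file headers. The submitters' processing notes name FastQC, Bowtie2 2.3.4.1 and MACS2 2.1.1 and the mm10 genome build, without the parameters. The list is part of a longer set of calls: the peak numbers in the deposited names run from 26 to 33876, so that the listed peaks make up 6.06% of the numbers. Its lowest −log10 p is 4.01, as a threshold on p would leave, but the scores of the unlisted calls are unknown. Other filters are not given in the sources used here. Peaks were called on 1 library against 1 control, so a score measures the excess of reads at a site in these libraries and not its reproducibility. Fold enrichments, summits, read counts and library depths were not used here, and the depth is unknown. Intervals on shares of peaks (95%, exact Clopper-Pearson) and on densities (95%, exact Poisson) cover counting error only. Neighbouring peaks are not independent, so tests that take single peaks as the unit tend to give p-values that are too small.

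Starts were raised by 1 to give 1-based positions, on the assumption that the list follows the BED convention, which the sources used here do not state, so that a start could be off by 1 base. Genes came from an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes, of which 21887 protein-coding genes on the autosomes, X and Y were used. The table gives each gene's start and end but no strand, transcript or exon, and no genome sequence was used here. The planned analyses of transcription start sites were therefore replaced by analyses of gene ends, where either end of a gene counts, and of gene bodies. The planned searches for TCF/LEF and other sequence motifs and the scan of short sequence words were not run, and neither were the tests that set peaks with a motif against peaks without one. For the same reason the positions of peaks are given as inside a gene or at a distance from it, and not as exon, intron or UTR.

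Each peak was assigned by its centre to the protein-coding gene whose body was nearest, within 50 kb. Of the peaks, 1668 were assigned. For each of 18 gene lists fixed before the data were examined, the number of members with at least 1 assigned peak was compared with 10000 random lists of the same size, matched in 20 bins on territory length, which is the stretch in which a gene is the nearest. The p-value is a two-sided permutation p, of which 0.0002 is the smallest these draws can give, with Benjamini-Hochberg adjustment over the 18 lists. The background was every protein-coding gene. Of the listed symbols, 2 (Ighm and Ahsp) had no protein-coding entry and were left out. Genes of 10 lists, those of T cells and the canonical Wnt targets, were pooled and are called the T cell set here. They were compared with genes of 5 lists of other lineages by a two-sided Fisher's exact test. The share of peaks near gene ends and inside genes was compared with 100 shuffles of the peaks over the annotated span of their own chromosome, with a smallest two-sided p of 0.02. This is called a permutation of positions here. A span runs from the first to the last protein-coding gene. Assembly gaps inside a span were not left out, although the plan named non-gap sequence. Some shuffled peaks could therefore fall where no peak can be called. Scores near gene ends and elsewhere were compared by a permutation test with 100000 resamples.

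Alternatives were assignment within 10 or 100 kb, gene bodies with 5 kb on either side, peaks above the median score (4.40) and unmatched lists. Added after the data were seen were gene ends in place of start sites, with the alternatives planned for those (another distance, the peak centre, all annotated genes, peaks above the median score), shares inside genes and far from them, peaks at or below the median score, distal peaks further than 2.5 kb from every gene end, autosomal peaks alone, lists without Tcf7 and Lef1, and local shifts of 20 to 200 kb as the null. The comparisons of X and Y with the autosomes, of scores with the position of peaks and with the T cell set, and the Poisson series of scores were also chosen after the data were seen. Ties at the median left 628 peaks above it and 1424 at or below it. Named were the 15 peaks with the highest score, the 10 genes with the most peaks, and of each list up to 4 members with the highest-scoring peak and up to 2 without a peak in alphabetical order, with Lef1, Tcf7, Cd4, Cd8a and Foxp3 in any case. Some genes that this rule takes are not reported here. The other genes named in the text are list members, genes of the chromosome Y test and 1 member of a gene family, and were chosen after their values were seen. The list test was tested on simulated data with all 21887 genes: with peaks at random positions 1 of 1800 lists was called, and a list with 8 members given a peak was called in 91 of 100 simulations. Random positions lack the gathering of the listed peaks at gene ends, so the rate of false calls for such peaks is not known from this. The 8 members were given a peak in addition to the random peaks, and smaller numbers were not simulated. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.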

Results

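Lef1 occupancy was mapped across the genome in conventional CD4+ T cells, the CD4 cells left when CD25-positive cells are excluded, from the spleens of wild-type C57BL/6 mice. Lef1-deficient CD4+ T cells, immunoprecipitated with the same antibody, gave the background. There was 1 library of each kind and no replicate. The deposited list held 2052 peaks covering 226879 bp, with a median width of 79 bp (range 55 to 1141 bp). Scores, given as −log10 p by the authors, ran from 4.01 to 38.17 with a median of 4.40. At a score of at least 8 there were 97 peaks, with a median width of 213 bp.

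Most peaks lay just above the threshold. The single score 4.40 was shared by 828 peaks, or 40.4% of the list (95% interval 38.2 to 42.5%). That score and the next ones in its series, 7 in all, equalled within 2e-05 the −log10 of the probability that a Poisson count with mean 0.364 exceeds 4 up to 10. The most common score stands for exceeding 4. Of the 12 starting counts tried, none but 4 matched more than 1 score. The read depth of the libraries is unknown.

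The first question was where in the genome Lef1 was found. Among the 15 highest-scoring peaks, 5 lay inside or within 50 kb of Dtx1, Satb1, Tcf7l2, Ptpre and Ptprc. A peak of score 18.29 lay inside Dtx1, which encodes a Deltex ubiquitin ligase (chromosome 5, 120685747 to 120686184, mm10). One of 16.36 lay 46.1 kb from Satb1, a chromatin organiser of T cells (chromosome 17, 51879334 to 51879541). One of 13.29 lay inside Tcf7l2, another member of the TCF/LEF family (chromosome 19, 55792536 to 55792921). Peaks also lay inside Ptpre (16.79; chromosome 7, 135542266 to 135542653) and Ptprc (12.57; chromosome 1, 138162616 to 138162965), which encode receptor-type tyrosine phosphatases, the latter CD45. A peak on chromosome Y at 261181 to 261271 had the same printed score, 12.57, and was not counted among the 15.

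Of the remaining 10 peaks, 5 were on chromosome Y, at 261326 to 261436 (score 38.17), 142873 to 143108 (29.07), 11858060 to 11858173 (18.85), 259109 to 259506 (17.23) and 140591 to 140697 (14.96). The peaks at 142873 and 140591 had the predicted gene LOC665918 as their nearest, at 29.1 and 26.7 kb. Another lay 15 kb from Dpy19l2 on chromosome 9 (20.87; 24542017 to 24542139). The last 4 had no protein-coding gene within 50 kb. They were on chromosome 4 at 64497856 to 64498057 (18.80), chromosome 10 at 117947985 to 117948295 (17.50), chromosome 15 at 59913962 to 59914216 (16.00) and chromosome 17 at 4908248 to 4908443 (13.63).

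Peaks gathered at the ends of genes. Within 1 kb of an annotated end of a protein-coding gene lay 433 peaks, or 21.1% (95% interval 19.4 to 22.9%), against 3.29% ± 0.404 (SD over 100 shuffles) for shuffled peaks, a ratio of 6.41 (permutation of positions, two-sided p = 0.02, the smallest the shuffles can give). When each peak was moved by 20 to 200 kb, the share near a gene end was 5.02% and the ratio 4.2 (permutation of positions, p = 0.02). Inside genes lay 1035 peaks, or 50.4% (48.3 to 52.6%), against 40.5% of shuffled ones (permutation of positions, p = 0.02), but against local shifts the ratio was 1.03 and the difference did not pass the test (p = 0.079). A further 633 peaks lay outside genes within 50 kb of one, and 384 peaks (18.7%, 17 to 20.5%) lay further away, against 35.4% of shuffled ones (permutation of positions, p = 0.02), a ratio of 0.528. Against local shifts, of which 21.2% lay as far, that ratio was 0.883 (permutation of positions, p = 0.02). As strand was not used here, 5' and 3' ends could not be separated.

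Peaks near gene ends made up 25.5% of those above the median score and 19.2% of those at or below it (Fisher's exact test, two-sided, p = 0.0015). Mean scores near gene ends (4.86) and elsewhere (5.02) did not differ by a permutation test (p = 0.095), and both medians were 4.40.

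The second question was which genes lay next to Lef1 peaks. The 1668 assigned peaks fell to 1461 genes, 6.68% of the protein-coding genes. Of these, 1281 had 1 peak, 159 had 2, 15 had 3 and 6 had 4. The genes with 4 were Satb1, Tcf7, which encodes the TCF/LEF family member Tcf1, Il6st, the shared signalling chain of the interleukin-6 receptor family, Sgms1, a sphingomyelin synthase, Tmem267 and LOC665918. The next by highest score, with 3 peaks each, were Dnaaf5 (9.30), Tagap (8.01), Rere (7.92) and Lef1 (7.65). Peaks were counted as listed, and close neighbours can be parts of a single site. At Il6st all 4 peaks lay in a stretch 36.3 to 39.1 kb from the gene, with a highest score of 8.72. All but the one at 112424758 to 112425090 lay between 112427441 and 112427814 on chromosome 13. The 3 peaks of Dnaaf5 lay between 139166996 and 139167535 on chromosome 5. At Sgms1 no peak scored above 4.40, and at Tmem267 the highest score was 12.22 over 81 bp.

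Genes of naive and quiescent T cells had the highest share of members with a Lef1 peak among the 18 lists, except by gene bodies with 5 kb on either side, where 37.5% of them and 40% of T cell identity genes had one. Of 24 members, 14 had a peak, against 2.39 for matched random lists, a ratio of 5.86 (permutation test, adjusted p = 0.0018). Satb1 had 4 peaks with a highest score of 16.36, and Tcf7 had 4 with a highest of 6.68. Lef1 itself had 3, the highest scoring 7.65, and Nsg2 had 1 of 8.01. Also among the 14 were Ccr7 (4.83), a chemokine receptor of naive T cells, S1pr1 (5.41), which guides exit from lymph nodes, and Bach2 (4.04), a transcriptional repressor. Bcl2 and Btg1 had none.

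At the genes of the family itself, the peaks of Tcf7 lay at chromosome 11, 52283322 to 52283412 (4.40) and 52284335 to 52284490 (5.53), next to the high-coordinate end of the gene at 52283383, and 26.2 kb (4.08) and 31 kb (6.68) beyond that end. At Lef1 the highest peak lay 4.26 kb below the low-coordinate end of the gene (chromosome 3, 131105853 to 131106225). The others lay inside it, at 131112055 to 131112109 (4.80) and 131190812 to 131190866 (5.41). Part of this gene is deleted in the control cells, and which part was not used here.

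**Figure D1:**
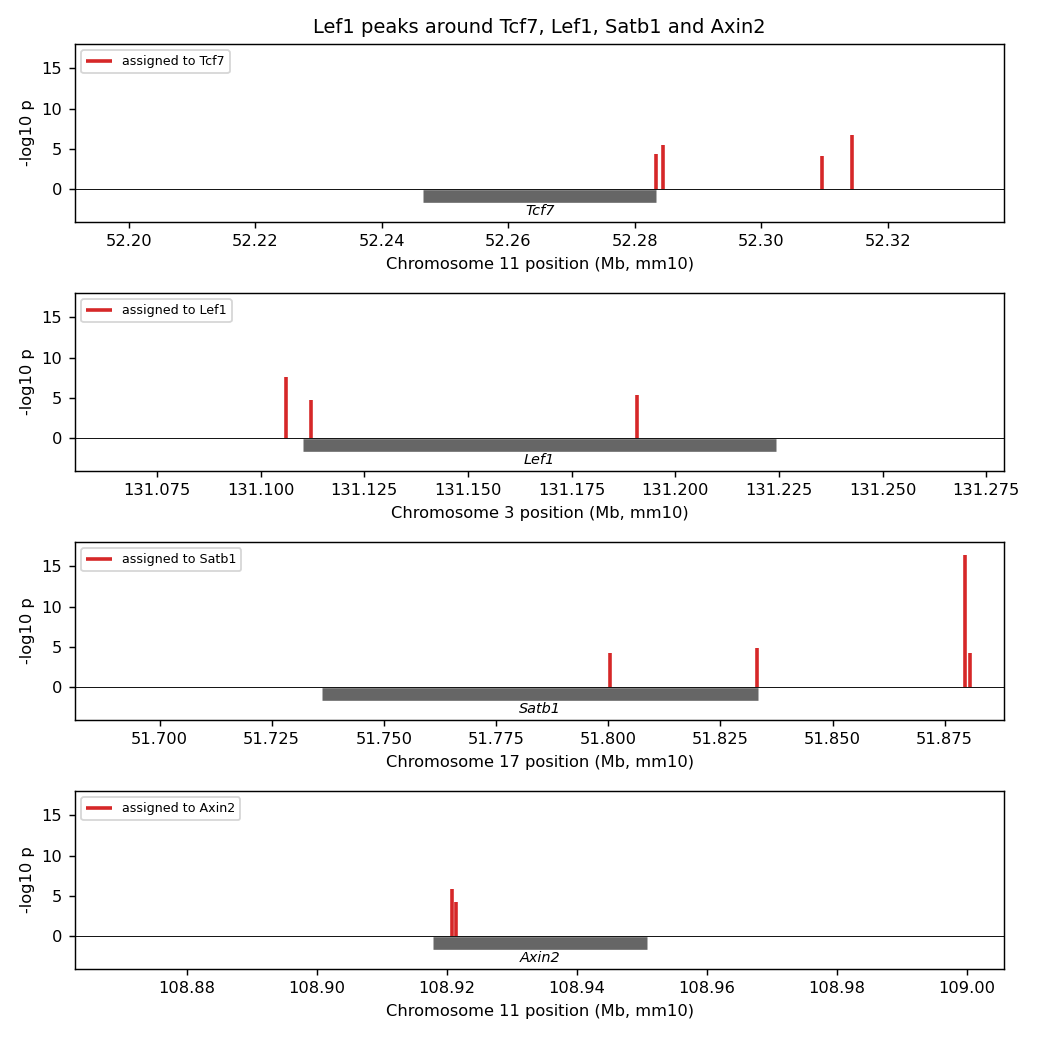
Lef1 peaks around Tcf7, Lef1, Satb1 and Axin2, drawn as vertical lines at each peak's centre whose height is the score (−log10 p), against mm10 position in Mb. Grey bars are gene bodies. Tcf7 and Satb1 have 4 peaks each, Lef1 has 3 and Axin2 has 2, and the highest line is the peak of 16.36 lying 46.1 kb from Satb1. Peaks are counted as listed, and those of Axin2 are close neighbours.

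T cell identity genes also had more members with a peak than matched genes. Of 25 members, 10 had a peak against 2.25 for random lists, a ratio of 4.45 (permutation test, adjusted p = 0.0018). They included Cd247 (7.22), which encodes the zeta chain, Zap70 (7.07, with 2 peaks) and Prkcq (6.95), and the adaptor gene Trat1 (5.63). The peaks of Zap70 were close neighbours (chromosome 1, 36767026 to 36767109 and 36767438 to 36767521). Those with no assigned peak included Cd2, Cd27 and Cd4.

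Canonical Wnt target genes had peaks at 8 of 20 members against 1.96 for random lists, a ratio of 4.09 (permutation test, adjusted p = 0.0036). Znrf3, a ubiquitin ligase that removes Wnt receptors, had 2 peaks with a highest score of 12.52, and its relative Rnf43 had 3 with a highest of 4.53. Axin2, a scaffold of the β-catenin destruction complex, had 2, of which the highest (5.86) was the widest peak of the whole list at 1141 bp (chromosome 11, 108920206 to 108921346). The other (4.28) lay directly beside it at 108921422 to 108921478, so both can be parts of a single site. At Rnf43 the peaks at 87721041 to 87721160 and 87721321 to 87721375 were close neighbours too. Tcf7l2 (13.29), Lef1 (7.65) and Cd44 (6.91) were further members, and Apcdd1 and Ascl2 were among those with none. Tcf7 and Lef1 are in this list, the naive list and the list of TCF/LEF partners. Without them 6 of 18 Wnt targets had a peak (permutation test, adjusted p = 0.048), 12 of 22 naive genes (0.0018) and 4 of 18 partners (0.68).

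Genes of follicular helper T cells had peaks at 6 of 20 members against 1.64 for random lists (permutation test, adjusted p = 0.039). The members with the highest scores were Il6st (8.72), the cytokine gene Il21 (6.84), the checkpoint receptor gene Pdcd1 (5.41) and Il6ra (4.99). Ascl2 and Batf had none. By the same permutation test this call was lost when peaks were assigned within 10 kb (4 members, adjusted p = 0.24) or 100 kb (6 members, 0.057), or by gene bodies with 5 kb on either side (4 members, 0.21). The ratios to random lists there were 3.11, 3.22 and 2.96, against 3.65. Partners of TCF/LEF factors and Groucho corepressors had peaks at 6 of 20 members and did not pass (permutation test, adjusted p = 0.072). Tcf7, Lef1 and Tcf7l2 were among them, as were Gsk3b (4.94), a kinase of the destruction complex, and Ctnnb1 (4.25), which encodes β-catenin. Apc and Bcl9 had none.

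No other list passed. Regulatory T cell genes had peaks at 3 of 20 members, namely Prdm1 (4.99), Gpr83 (4.40) and Ctla4 (4.20), against 1.53 for random lists (permutation test, adjusted p = 0.9), and Foxp3, Ebi3 and Entpd1 had none. Foxp3 lies on chromosome X, where peaks were scarce in general, so its lack of a peak says little. Genes of the response to T cell receptor signals had 4 of 25 (0.69), with Dgka, a kinase that removes diacylglycerol, at 12.45, Cblb at 5.63 and Rel and Nfatc1 at 4.40, and none at Cd5 or Cd69. Th1 genes had 2 of 15, Stat4 (4.37) among them, with none at Ccl5, and Th2 genes had 1 of 15, Il4ra (8.74), with none at Bhlhe41 or Ccr4. Th17 genes had 0 of 14, Ahr and Batf among them. CD8 and cytotoxic T cell genes had 0 of 20, with Cd8a, Cd160 and Ccl5 among them. For these 4 lists random lists had means between 0.826 and 1.1, so that a count of 0 does not differ from them (permutation test, adjusted p = 0.9 for both of the lists at 0).

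**Figure D2:**
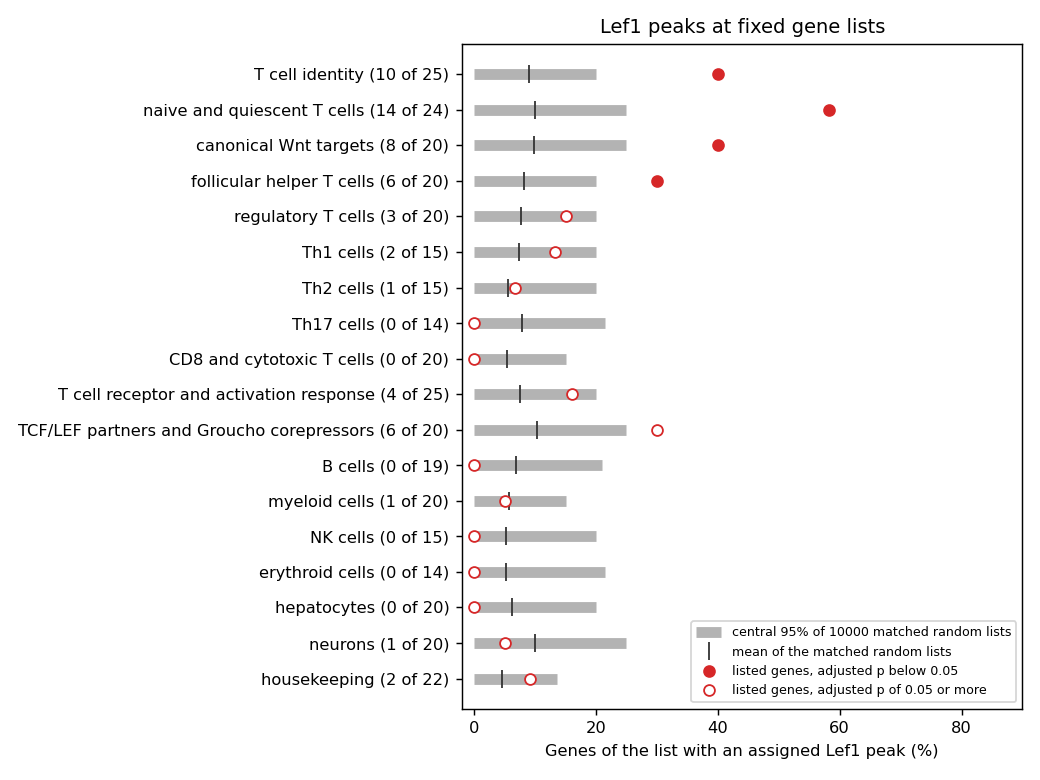
Share of each fixed list's genes with an assigned Lef1 peak (%), as points, filled where the adjusted p is below 0.05, with the mean (tick) and the central 95% (bar) of 10000 random lists matched on territory length. The naive list stands at 58.3%, the T cell identity and Wnt target lists at 40%, and the lists of other cell types at 5% or less.

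Lists of markers of other cell types did not differ from random lists (permutation test, adjusted p = 0.9 to 1), but random lists had means of 0.729 to 2, so that a count of 0 could not have passed as lower. B cell genes had 0 of 19, Bank1 and Blk among them. NK cell genes had 0 of 15, such as Cd244a and Cd7, and erythroid genes 0 of 14, such as Alas2 and Ank1. Myeloid genes had 1 of 20, Fcgr3 (4.40), with none at Adgre1 or Cd14. Of tissues outside the blood, hepatocyte genes had 0 of 20, Ahsg and Alb among them, and neuronal genes 1 of 20, with none at Camk2a or Dlg4. Housekeeping genes had 2 of 22, Psmb2 (4.40) among them, with none at Actb or B2m, against 0.995 for random lists (permutation test, adjusted p = 0.9).

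Taking the 10 T cell and Wnt lists as one set, 46 of 187 genes (24.6%) had a peak, against 2 of 93 genes (2.15%) of B, myeloid, erythroid, liver and neuronal lists (Fisher's exact test, two-sided, p = 3.7e-07). Matched genes had peaks in 7.95% and 6.9% of cases, so that the difference of 22.4 percentage points stood against 1.1 for matched sets (permutation test, p = 0.0002, the smallest the draws can give). The set of other lineages alone stood at a ratio of 0.312 to matched genes and did not pass (permutation test, p = 0.07). Peaks of higher score lay at the T cell set more often. Of the 628 peaks above the median score, 41 (6.53%) were assigned to it, against 28 of the 1424 at or below it (1.97%; Fisher's exact test, two-sided, p = 7.4e-07). Some of these peaks are neighbours at the same gene and are not independent, so this p is too small. With the lower-scoring peaks alone 23 of 187 genes of the T cell set (12.3%) had a peak, against 2 of 93 (2.15%; Fisher's exact test, two-sided, p = 0.0035). No single list passed with them, and the naive list had 6 of 24 members, a ratio of 3.5 (permutation test, adjusted p = 0.21).

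Peaks were unevenly spread over chromosomes. Autosomes held 2018 peaks, or 0.831 per Mb, with single autosomes between 0.659 and 1.19. Chromosome X held 15, or 0.0879 per Mb (95% interval 0.0492 to 0.145), where the autosomal density would give 141.8. The ratio was 0.106 (0.0591 to 0.175; exact binomial test, two-sided, p = 3.36e-40). Chromosome Y held 19 peaks, or 0.209 per Mb, a ratio of 0.252 (0.151 to 0.395; exact binomial test, two-sided, p = 4.79e-14). Per protein-coding gene the ratio was 0.76, which did not differ from the autosomes (0.457 to 1.19; exact binomial test, two-sided, p = 0.267), while that of X was 0.159 (0.0888 to 0.263; p = 3.78e-23). On Y 10 peaks (52.6%) scored at least 8, against 87 of the autosomal peaks (4.31%; Fisher's exact test, two-sided, p = 2.4e-09). The 19 peaks on Y lay at 8 separate places, several of them bunches of neighbours. They are not independent, so this p is too small. Without the peaks on X and Y the same number of T cell set genes, 46 of 187, had a peak, while genes on X stayed in the lists. Random lists were not matched on chromosome, so list members on X, such as Foxp3 and Alas2, had little prospect of a peak.

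**Figure D3:**
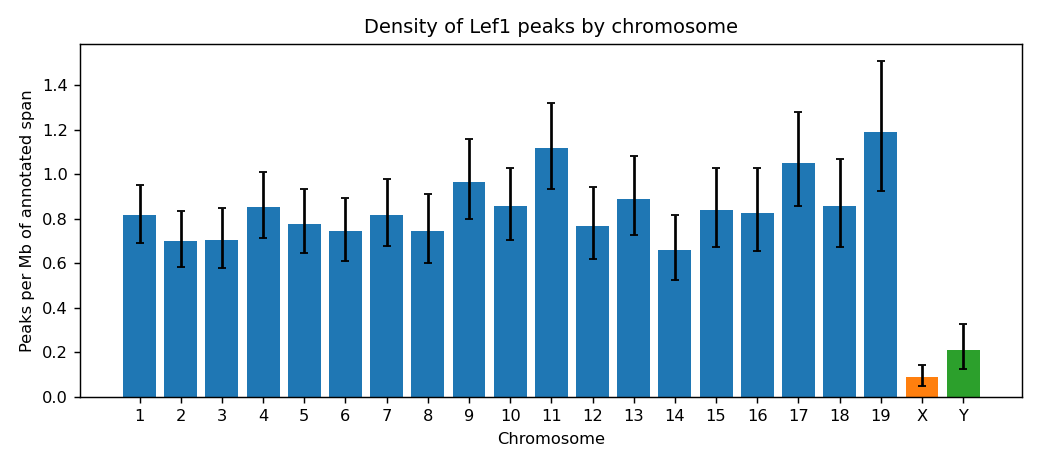
Lef1 peaks per Mb of annotated span for each chromosome, with exact 95% Poisson intervals as error bars. The autosomes lie between 0.659 and 1.19 peaks per Mb, chromosome X at 0.0879 and chromosome Y at 0.209.

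**Figure D4:**
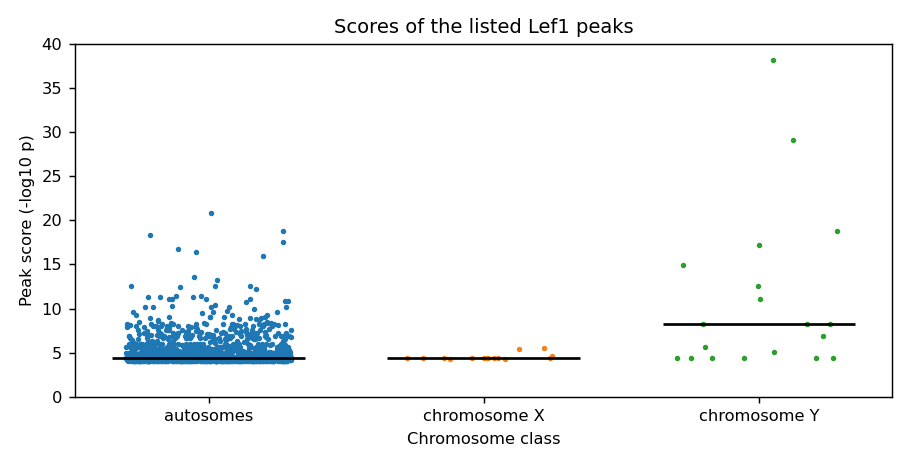
Score (−log10 p) of every listed peak on the autosomes, X and Y, 1 point per peak with random horizontal spread, and a black line at the median. The medians are 4.40 on the autosomes and on X and 8.26 on Y, where the highest score of 38.17 lies.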

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

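Chosen after the data were seen were gene ends and shares inside genes in place of transcription start sites, local shifts, lower-scoring, distal and autosomal peaks, and lists without Tcf7 and Lef1. Of the 162 repeats of single lists, 151 kept their side of the threshold, 7 lost it and 4 gained it. No call past the threshold turned its direction, while the ratios of the regulatory T cell, Th2, myeloid and housekeeping lists, which never passed, lay on either side of 1. The naive, T cell identity and Wnt target lists passed the permutation test in every repeat except with peaks at or below the median score, which left 6 (adjusted p = 0.21), 4 (0.78) and 4 (0.78) members with a peak and 0 lists in all, against 4. No list test there reached an adjusted p of 0.05 by permutation, and the naive list had a ratio of 3.5 and an unadjusted p of 0.012. The follicular helper list lost its call with 4 members within 10 kb, 6 within 100 kb, 4 by gene bodies and 3 with the lower-scoring peaks. The list of TCF/LEF partners gained its call with 7 members within 100 kb, 4 above the median score, 6 in unmatched lists and 6 with distal peaks, but had 4 of 18 (permutation test, adjusted p = 0.68) without Tcf7 and Lef1. The cause was not tested. The T cell set stayed above other lineages in all 7 alternatives, by 10.1 to 23 percentage points. The share of peaks inside genes, 50.4%, did not pass against local shifts, while the share near gene ends passed throughout. The list shrank to 628 peaks above the median score and 461 above the upper quartile, and merging peaks within 1 kb left 1954. No paired analysis was possible because each group has 1 library and only 1 of the libraries has a peak list, and leaving out a replicate was not possible either. The depth of the libraries is unknown, and a gene without a peak is one with none past this threshold. Motif searches and their alternatives, and every alternative for transcription start sites, were not run for lack of sequence and strand.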

Other observations

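The tests on the sex chromosomes and on gene families were chosen after the results were seen, and the criterion of the test on low-scoring peaks was changed after its result was seen. The T cell receptor α locus (Tcra, chromosome 14, 52427967 to 54224198) held 5 peaks with a highest score of 11.09, and Tcrb held 2 of at most 4.40. The immunoglobulin loci Igh and Igk held 1 peak each (4.40 and 4.09), and Tcrg and Igl held 0. Differences between these loci were not tested.

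Among 153 gene families of at least 15 protein-coding members with the same leading letters in their symbols, 2 passed by permutation against matched genes, and both had fewer peaks. Olfactory receptor genes (Olfr) had a peak at 5 of 1110 members, against 42 for matched genes (permutation test, adjusted p = 0.015). Vomeronasal receptor genes (Vmn) had 5 of 355, against 21.9 (permutation test, adjusted p = 0.015). The protein phosphatase genes (Ppp) had 14 of 77, against 5.24, among them the calcineurin subunit gene Ppp3r1, and did not pass (permutation test, adjusted p = 0.082). Members of both receptor families resemble one another closely, and whether reads at near-identical copies were kept is not given in the sources used here.

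The excess of peaks at T cell gene lists was set against technical explanations. Open promoters at annotated gene ends were argued against by distal peaks: with those further than 2.5 kb from every gene end, 12 of 24 naive genes had a peak against 1.82 for matched genes (permutation test, adjusted p = 0.0024). Housekeeping genes had 0 of 22 there, against 0.494, and by gene bodies with 5 kb on either side 4 of 22, a ratio of 3.76 that did not pass (permutation test, adjusted p = 0.13, unadjusted p = 0.036). Promoters inside genes stay open, since 690 of the 1486 distal peaks lay inside a gene and no transcripts were used here. Loss of DNA from the control at the deleted Lef1 gene could bear only on Lef1 among the naive genes, so it does not account for the excess. Without Tcf7 and Lef1 12 of 22 naive genes had a peak (permutation test, adjusted p = 0.0018). Leaving out so few genes could hardly have changed the call, so that repeat adds little. The peaks at Lef1 itself stay open to such a loss. Whether the low-scoring peaks are background stays open. As first written, the test asked only whether the naive list passed with them, and it did not (6 members, a ratio of 3.5, permutation test, adjusted p = 0.21, unadjusted p = 0.012), which met the form written for background. Against random positions stand the condition added afterwards, on values already seen, that 19.2% of them lay within 1 kb of a gene end against 3.21% of shuffled ones, and the T cell set (12.3%) above other lineages (2.15%; Fisher's exact test, two-sided, p = 0.0035). Background from open chromatin could give both. Distal chromatin that is open in T cells without Lef1 was not tested, as no other assay was used here, and the biological reading, that Lef1 occupies genes of naive T cells and its own pathway, remains a hypothesis from 1 library.

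The low number of peaks on chromosome X is not what a low gene density would give, since peaks per protein-coding gene were also lower there, at a ratio of 0.159 to the autosomes (95% interval 0.0888 to 0.263). Whether the ChIP cells had 1 copy of X, so that fewer reads left fewer sites above a fixed threshold, stays open. The density ratio of 0.106 (95% interval 0.0591 to 0.175) is the scarcity itself, and a true lack of Lef1 sites on X would give the same value. In the longer set of calls X was sparse too. The numbers in the deposited names, taken to follow position, leave at most 2.89 calls per Mb of X, against 13.7 on the autosomes. The scores of the unlisted calls are unknown, so this does not decide it either. The labels used here do not give the sex of the mice. Chromosome Y held 19 peaks, 10 of them scoring at least 8, as ChIP cells with a Y and 1 X could give. Duplicated sequence on Y stays open as their source, so they do not settle the number of X copies.

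The high-scoring peaks on chromosome Y came in bunches. The first bunch of 4 peaks (140591 to 145008) and the second of 6 (258183 to 263634) shared mirrored spacings: all 4 peaks of the first met a peak of the second within 25 bp under a single reflection, against a mean of 1.63 for random positions (permutation of positions, p = 0.0001 in 10000 draws, the smallest they can give). The reflection left 2 of the 6 peaks of the second bunch without a partner, among them the one with the highest score of the list (261326 to 261436, 38.17). That peak lay directly beside a peak with a partner, at 261181 to 261271. Its lack of a partner within 25 bp therefore does not place it outside the mirrored stretch. The spacing was noticed before it was tested and the tolerance set after, so duplicated sequence, from which reads of several copies could pile up, stays open. Whether the control library lacked a chromosome Y, which would also leave such a pile-up without a matching background, cannot be told either, because 0 of 8 single-copy Y genes such as Ddx3y and Uty had a peak within 50 kb and Lef1 need not bind there.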
